A study of Methanothermobacter thermautotrophicus and Methanothermobacter marburgensis with 12 samples.

How the data were processed

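RNA was sequenced from 12 continuous bioreactors, 4 for each of 3 methanogenic archaea: Methanothermobacter thermautotrophicus ΔH, M. thermautotrophicus Z-245 and M. marburgensis Marburg. Per the labels, the cultures grew in minimal medium on a gas feed of 80% H2 and 20% CO2 and were sampled on day 7, after 2.7 days at steady state. Per the labels' protocols, RNA was extracted with hot phenol, and libraries were made from 100 ng of RNA with a stranded total RNA kit that depletes ribosomal RNA. The labels call the reactors of a strain biological replicates, and each library comes from its own reactor. The reactor identifiers begin with S1 or S2, taken here as 2 reactor sets. Set S1 held 2 ΔH reactors, 1 of Z-245 and 1 of Marburg, and set S2 held 2, 3 and 3. Set and strain are thus partly confounded.

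The authors deposited a quantification table per reactor. Per the file headers, each table holds a feature's length, its effective length, its TPM and its estimated count of reads. The estimated counts are not whole for every feature, and TPM sums to the same total over the features of a library. The submitters' processing notes name BWA 0.7.17, featureCounts, Subread 2.0.1, Salmon 1.5.2 and DESeq2 1.32.0, with no role or order. The genome builds, the annotation and the strand setting of the counting are not given in the sources used here. Length is the same in the 4 tables of a strain, and effective length differs between libraries. The tables list 1796 features for ΔH, 1804 for Z-245 and 1730 for Marburg, under locus tags of each strain's own.

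The files do not pair these identifiers with gene names, nor the identifiers of one strain with those of another. The design fixed before the data were examined called for an edgeR quasi-likelihood test between strains over features paired by the files or by a reference, and for no test if no such pairing was given. It was not given, so the main results are the levels within each strain and the composition of the libraries. Tests of single features between strains, which depart from this design, stand only in the closing section. The gene lists, the named genes chosen by function and the isoenzyme ratios planned then need gene names and were not run. Ribosomal and transfer RNA could not be told from other features, so every feature stayed in the library totals.

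Depth was the sum of estimated counts, between 9044084 and 13106122 reads per library. A count of 0 allows a level of up to 3 reads. This floor covers counting error only. Levels are the deposited TPM as mean ± SD over 4 reactors. Composition measures (3 in all) were compared between strains: the percent of reads in the 10 most counted features, the percent of features at 0 reads and the percent of features below 1 TPM. Each comparison used an exact two-sided permutation test of 4 against 4 reactors, for which the smallest possible p is 0.0286, with Benjamini-Hochberg adjustment over 9 comparisons. These tests were chosen after the data were seen, and they took no account of the reactor set. Agreement of replicates was Pearson's r of log2(TPM + 1) across features. No 2 replicate tables agreed within sampling noise in a chi-square test of their counts.

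For the closing section alone, features were paired between strains by an alignment of feature lengths in identifier order. This departs from the fixed design and was devised after the data were seen. Equal lengths scored 5, lengths within 3% scored 2, others -5 and gaps -2. A single set of scores was tried. The Marburg order was aligned first as deposited and then rotated to the start with the highest score. On a simulated copy of the ΔH feature lengths, altered and rotated, 99.8% of the 1632 pairs made were right. The copy kept most lengths equal, and apart from rotation its order was not rearranged. Of the real pairs, 68.3% had equal length between ΔH and Z-245 but 42.7% between ΔH and Marburg. The simulation therefore does not give the accuracy of pairs with Marburg. On the paired features, edgeR's quasi-likelihood test was run on estimated counts rounded to whole numbers, with TMM scaling, effective-length offsets, its default expression filter and all 12 libraries in the fit. A fit on the 8 libraries of a pair was also run before the 12-library layout, the one the design names, was kept. Adjusted p-values are Benjamini-Hochberg. On simulated counts for ΔH against Z-245, 1359 features were tested. The test called 99.0% of 100 features changed by 1 on the log2 scale and 100% of 100 changed by 2. Of its calls, 4.33% were false. The changed features were drawn from those with a mean of at least 20 reads in ΔH. Every feature was given a dispersion of 0.03, a measure of the spread between replicates. The shares called therefore do not cover features with fewer reads, and no rate covers libraries that deviate from their strain. Features were chosen for naming by the largest fold among those with an adjusted p under 0.05, a change of at least 2-fold, no overlap between the strains and a mean of at least 20 TPM in the higher strain. The rule fixed beforehand also asked for an annotated function, which was dropped, and the names were limited to 2 higher and 2 lower features per pair. Alternatives were other scalings, DESeq2, limma-voom, other count filters, no length offset, a replicate block, the reactor set as a covariate, reactors of a single set, and each replicate left out.

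Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.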

Results

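The transcriptomes of 3 hydrogenotrophic methanogens, archaea that make methane from H2 and CO2, were measured in continuous bioreactors at steady state. Each strain had 4 reactors. The libraries held 10088684 ± 814421 reads for ΔH, 9432553 ± 349432 for Z-245 and 12828542 ± 313886 for Marburg (SD, n = 4). The study set out to describe expression in each microbe and to compare the microbes. The files do not pair feature identifiers with gene names or between strains, so features are given by their identifiers. Single features are not compared between strains here. Lengths were a multiple of 3 for 64.3% of features in ΔH, 65.7% in Z-245 and 66.1% in Marburg. Features are thus not taken to be whole protein-coding genes. Levels displaced from identifiers or counted on the opposite strand, taken up in the closing section, could not be excluded.

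In ΔH, a few features held most of the TPM and of the counted reads. The 6 highest features took 89.0% ± 1.60 of the TPM and 91.8% ± 1.18 of the reads (SD, n = 4). The highest was ISG35_08555, 540 bases long, at 345292 ± 9992 TPM, followed by ISG35_08560 at 157462 ± 3929 TPM (SD, n = 4). The median feature stood at 12.1 TPM, and 457 of 1796 features had a mean below 1 TPM. Of these, 44 had no read in any of the 4 reactors.

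Z-245 had the same kind of distribution. Its 6 highest features took 85.9% ± 2.40 of the TPM and 87.7% ± 2.37 of the reads (SD, n = 4). ISG36_08595 was highest at 256828 ± 8770 TPM and ISG36_08600 next at 203587 ± 6854 TPM (SD, n = 4). The median feature stood at 13.4 TPM, 488 of 1804 features had a mean below 1 TPM, and 67 had no read in any reactor.

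In Marburg, the 6 highest features took 65.2% ± 5.71 of the TPM and 83.6% ± 3.08 of the reads (SD, n = 4). ISG34_02320, 2044 bases long, was highest at 195346 ± 16752 TPM and took 45.8% ± 1.74 of the reads, and ISG34_02315 stood at 166883 ± 22256 TPM (SD, n = 4). The median feature stood at 72.0 TPM. Only 8 of 1730 features had a mean below 1 TPM, and 1 had no read in any reactor.

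The share of features at 0 reads was 8.37% ± 1.55 in ΔH, 8.20% ± 0.661 in Z-245 and 0.303% ± 0.0727 in Marburg (SD, n = 4). Every ΔH and Z-245 library lay above every Marburg library. The exact two-sided permutation p was 0.0286 for each of these strains against Marburg, the smallest that 4 against 4 reactors can give. It was 0.0643 after adjustment over 9 comparisons, so the difference did not pass the correction. At the smallest possible p, passing depended on how many of the other comparisons also reached it. The outcome therefore does not weigh the size of the difference. ΔH and Z-245 differed by 0.162 percentage points, less than the spread between reactors (exact permutation p = 0.886, adjusted p = 0.886). The share of features below 1 TPM was 25.5% ± 3.01 in ΔH, 26.5% ± 1.80 in Z-245 and 0.621% ± 0.128 in Marburg (SD, n = 4), with the same exact permutation p of 0.0286 and adjusted p of 0.0643 for each strain against Marburg, and an exact permutation p of 0.6 (adjusted p = 0.675) between ΔH and Z-245. TPM is a share of a fixed total, of which the 6 highest features took 89.0% in ΔH, 85.9% in Z-245 and 65.2% in Marburg. A level of 1 TPM is thus not the same part of the remaining total in each strain. The features are those of each strain's own annotation, and the strand setting of the counting is not given in the sources used here.

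**Figure D1:**
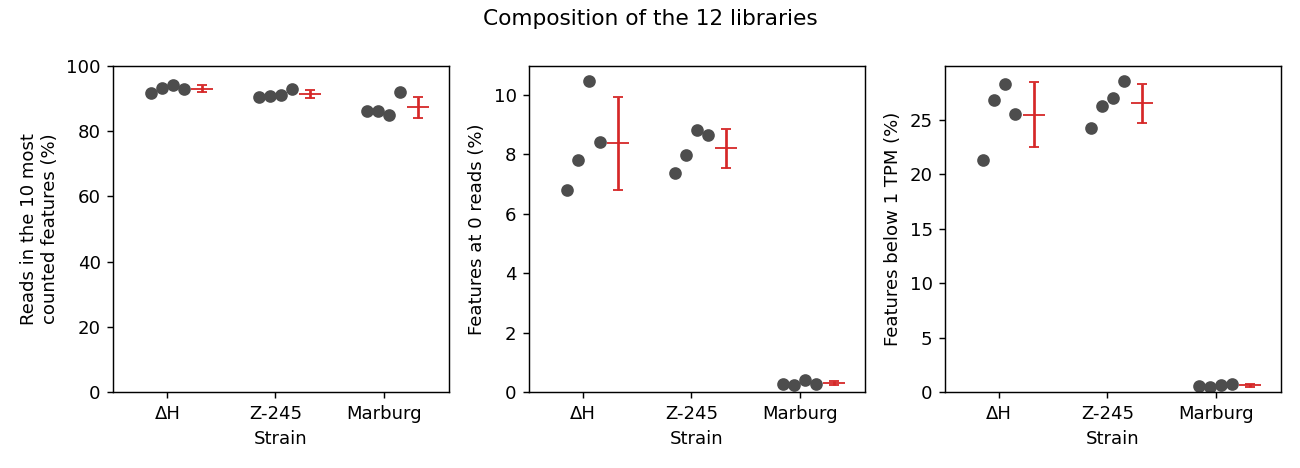
Each point is a library, and the red bar and whiskers are the mean and SD of 4 reactors; the panels show, in percent, the reads in the 10 most counted features, the features at 0 reads and the features below 1 TPM. Marburg libraries lie between 0.231% and 0.405% of features at 0 reads, and ΔH libraries between 6.79% and 10.5%.

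The 10 most counted features took 92.9% ± 1.08 of reads in ΔH, 91.3% ± 1.12 in Z-245 and 87.3% ± 3.21 in Marburg (SD, n = 4). None of the 3 differences passed the test. The exact permutation p was 0.0571 for ΔH against Z-245 (adjusted p = 0.0857), 0.0571 for ΔH against Marburg (adjusted p = 0.0857) and 0.114 for Z-245 against Marburg (adjusted p = 0.147). This share leaves 603276 to 773286 reads per ΔH library for all other features, against 1006049 to 1987844 per Marburg library.

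Replicate reactors agreed closely across features, which are not independent replicates. The mean r of a library with the other reactors of its strain was 0.984 to 0.988 in ΔH, 0.978 to 0.988 in Z-245 and 0.956 to 0.979 in Marburg. The lowest was Marburg replicate 4, at 0.956, which also had a median of 194 reads per feature where the other Marburg libraries had 385 to 466.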

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

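The thinning test below was chosen after the low agreement of a Marburg library was seen, and its bounds were set before its own result was seen. Among 48 groups of 4 reactors, 3 values lay far from the other reactors of their strain, where chance gives about 1 in 20, or 2.4. In Z-245 replicate 4, ISG36_04760 stood at 4439 TPM against 17476 to 18658 in the other reactors, and ISG36_04765, the next identifier, stood at 2506 TPM against 9966 to 10609. In Marburg replicate 4, ISG34_08875 stood at 2415 TPM against 7384 to 8178.

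Marburg replicate 4 agreed least with its strain (mean r 0.956). A candidate explanation was its smaller number of reads outside the leading features. After the other Marburg libraries were thinned to that number, their mean r with each other was 0.984, against 0.987 before, so fewer reads do not account for the gap. No biological explanation was tested, since the labels give this reactor no condition of its own.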

How the results depend on the processing

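The pairing behind the counts of changed features was chosen after the data were seen, as were 4 of the alternatives: equal lengths only, the libraries that agree least left out, the leading features left out and window 12 of the order left out. For composition, thinning and the single reactor set were added likewise. With at least 50 reads in every strain mean, 662 features were tested. The counts then were 350 changed and 143 at least 2-fold for ΔH against Z-245, 580 and 458 for ΔH against Marburg, and 590 and 456 for Z-245 against Marburg. With equal lengths alone, 499 were tested, and the counts were 250 and 161, 450 and 389, and 446 and 399. Both test fewer features, and none named between ΔH and Z-245. The other 132 of 144 alternative counts stayed within 1.5 times. The direction of calls against Marburg depended on the setting: 41.6% of 2-fold calls were higher in ΔH, but 15.6% with library size alone, where the median log2 fold change was -2.32 and not -0.44. For Z-245 these shares were 43.2% and 18.9%. The 50-read filter gave 80.3% and 81.8%, but it leaves out features near 0 in ΔH or Z-245, which largely fixes that direction. With a replicate left out, the counts ranged from 607 to 661 and 407 to 419 for ΔH against Z-245, 1213 to 1235 and 1077 to 1088 for ΔH against Marburg, and 1242 to 1265 and 1091 to 1103 for Z-245 against Marburg. With replicate 4 of Z-245 and replicate 4 of Marburg both left out, they were 735 and 415 for ΔH against Z-245. All 262 alternative fold changes fitted for named features kept direction and call, as the largest folds nearly must. Same-numbered reactors did not deviate together (median correlation -0.00478, 1 of 12 pairs over 0.1, 3 of 12 libraries correlating best with their own number), and with the replicate block the counts were 645 and 415, 1221 and 1078, and 1250 and 1093.

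The difference between ΔH and Z-245 in features at 0 reads turned to -0.404 after thinning to equal reads outside the leading features, where the differences from Marburg were 8.55 for ΔH and 8.96 for Z-245. The difference between ΔH and Z-245 ranged from -0.539 to 0.686 with a replicate left out. It was 0.956 with the reactors of set S2 alone, against 0.162 with all. That in features below 1 TPM ranged from -1.96 to 0.359. Neither was called. Gene lists, isoenzyme ratios and levels without RNA genes were not run.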

Other observations

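The pairing of features by length and order used in this part was devised after the data were seen, as were the comparisons of levels, displacements and neighbours. The edgeR test and its layout were fixed beforehand, but running it on this pairing departs from the design, which called for no test of single features between strains unless the files or a reference paired them. The pairing gave 1651 pairs between ΔH and Z-245, of which 1128 had equal lengths, against 494 and 44 with the order reversed. ΔH and Marburg gave 1434 pairs, 612 of equal length, against 485 and 35 reversed. All 3 alignments agreed on 1381 features.

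The 6 highest features of ΔH were paired with the 6 highest of Z-245. None was paired with one of the 6 highest of Marburg, but ISG35_08550 had no partner in Marburg, and ISG34_02320, the highest in Marburg, had none in ΔH or Z-245. The ΔH partners of the other leading Marburg features lay at nearby, earlier identifiers. They were ISG35_08445 and ISG35_08450, before ISG35_08535 to ISG35_08560, and ISG35_09085 to ISG35_09100, before ISG35_09205 to ISG35_09220. No displacement was tested on the leading features alone. Across the 1381 features, which are not independent replicates, Spearman's rho of mean TPM was 0.807 between ΔH and Z-245, 0.0787 between ΔH and Marburg and 0.0311 between Z-245 and Marburg. The 139 highest of these features in ΔH shared 102 with the 139 highest in Z-245 and 19 with those in Marburg, where about 14 would be shared by chance.

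Technical explanations of this gap could be weighed in part. A wrong pairing is argued against only in part by the lengths. At least 604 pairs with Marburg had equal length, against 35 with the order reversed. However, the alignment favours equal lengths, and these 604 are 42.3% of the 1429 pairs of Z-245 and Marburg. Over the 501 features of equal length in all 3 strains, rho was 0.808 between ΔH and Z-245. It was 0.135 between ΔH and Marburg and 0.0539 between Z-245 and Marburg. Few reads are argued against by the rho of 0.807 between the strains with the fewest reads outside the leading features. Levels displaced from their identifiers stay open: over all displacements of the Marburg order, the rho with ΔH was highest at 5 features, at 0.194, above the 0.123 reached at any displacement beyond 80, but far below 0.807. With a displacement that could vary between 13 windows of 100 features, the mean rho was 0.293, where 1000 random offsets gave 0.224 on average and at most 0.272 (permutation p = 0.001, the smallest they can give). Counting of the opposite strand in some strains' files stays open too, since the files used here give no strand. Of the 139 highest in Marburg, 37 lay below 1 TPM in ΔH, close to the 25.1% of all paired features, and of the 139 highest in ΔH, 0 lay below 1 TPM in Marburg, where 0.362% of all did, so neither count decides. Neither explanation can be told apart from a difference between species, which was not tested.

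With that limit, edgeR's quasi-likelihood test on 1357 features called 653 between ΔH and Z-245 (315 higher and 338 lower in ΔH), 420 of them at least 2-fold (184 higher and 236 lower). With all 12 libraries, the expression filter can keep features through Marburg reads alone. The fit on the 8 libraries of this pair, over all 1651 pairs of the 2 strains, tested 1182 features. It called 748, of which 435 at least 2-fold. The calls of at least 2-fold were more often lower in ΔH in every setting. For calls of any size the direction depended on the setting: 335 were higher and 328 lower with RLE scaling, 347 and 333 with DESeq2, 139 and 111 with equal lengths alone, and 192 and 294 with library size alone. The test with all 12 libraries called 1232 between ΔH and Marburg (1077 at least 2-fold) and 1254 between Z-245 and Marburg (1092 at least 2-fold). The latter counts follow from levels that are almost unrelated, and may be technical for the reasons weighed above (rho of 0.194 at the best single displacement of the whole order). Of the 35 splits of the 8 libraries of each pair, only the real one, 1 split, gave as many calls at either threshold. The highest other count in edgeR was 0 in every pair, with up to 184, 63 and 108 features at an unadjusted p under 0.05. Every other split puts both strains in each group, which widens the spread within groups, so these zeros do not show whether chance can be excluded. A difference in how the files were made is confounded with strain.

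Between ΔH and Z-245, ISG35_04390 rose to 888 ± 282 TPM in ΔH against 0.204 ± 0.262 in Z-245 (SD, n = 4), a ratio of 4365 with a counting interval of 1514 to 21451. It rests on 3 reads in the 4 Z-245 libraries, and without Z-245 replicate 1 its fitted log2 fold change was 12.91, against 11.92 with all. ISG35_07810 was at least 82.9-fold higher in ΔH, and the partners of ISG35_07615 and ISG35_07605 were at least 714-fold and 62.1-fold higher in Z-245, against a floor of 3 reads per library. The last 3 lie in a single stretch of 100 paired features, the twelfth of 13 windows along the order. There the rho between ΔH and Z-245 was 0.202, against 0.650 to 0.926 in the other windows. In this stretch 63 of 100 features were called at least 2-fold, against 28.4% elsewhere. It was singled out after its low rho was seen, so the larger share of calls follows largely from that choice. A displacement of 1 gave a rho of 0.288 there. A wrong pairing within the stretch was not tested, so these 3 folds may not compare the same feature. Without this stretch 354 features were called at least 2-fold. Against Marburg, ISG35_08555 stood at 345292 ± 9992 TPM in ΔH and its partner at 72.1 ± 28.7 TPM in Marburg, while ISG35_09090 stood at 0.158 ± 0.142 TPM against 53802 ± 4281 TPM (SD, n = 4). The latter's fitted log2 fold change rests on 7 reads in ΔH and was -16.23 without ΔH replicate 4, against -16.84 with all. With library size alone, which like TPM has no scaling for composition, the fitted values of these 2 features were 12.25 and -18.50, against 14.18 and -16.84.

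Features changed at least 2-fold lay next to features changed the same way more often than in shuffled orders. Between ΔH and Z-245 there were 177 such neighbours, against a mean of 64.6 in 10000 shuffled orders (permutation p = 0.0001, the smallest they can give). The counts were 610 against 431 for ΔH and Marburg and 637 against 439 for Z-245 and Marburg, each with a permutation p of 0.0001. Within each strain, levels already correlated with those of the next feature (Spearman's rho 0.434 in ΔH, 0.444 in Z-245 and 0.549 in Marburg). Shuffled orders do not keep that correlation, so the small p-values follow largely from it and do not decide between causes. Neighbouring genes transcribed together may give such runs, and so may, in the pairs with Marburg, stretches whose levels are displaced from their identifiers. Between ΔH and Z-245 the best displacement was 0 in 12 of 13 windows, so displacement is no general explanation of the runs there.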
